A study of Mus musculus with 24 samples.

How the data were processed

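RNA from bone marrow derived macrophages of 24 cultures, 4 biological replicates of each of 2 genotypes (WT floxed controls and KO with myeloid deletion of Slc2a1) in 3 states (M0, M1 and M2), was hybridised to Agilent mouse arrays. RNA was purified on columns and labelled with Cy3 by a low-input amplification kit, per the labels' protocols. Images were read with Agilent Feature Extraction 10.7.3.1, per the file headers, whereas the submitters' processing notes name version 9.1. The deposited scanner files, 1 per array, held 62976 spots, of which 3671 were controls and 59305 belonged to 56605 gene probes, and 0 gene spots were saturated. The processed signal is an intensity in linear units that was background-subtracted, spatially and multiplicatively detrended within the array and replaced by a surrogate value near background, per the file headers; it was not normalized between arrays. Probe coordinates were on mm9.

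These processed intensities were the only kind of value used. A deposited value table of intensities with 56745 entries for the same arrays was compared with the scanner files: 56305 entries (99.2%) equalled the 24 values of a single spot within 1 part in 10000, but in 0 of them did the identifier belong to the probe of that spot, and by identifier the correlation of log2 values on an array was 0.0279 to 0.0769. The table was therefore not analysed by gene. The column medians of the table in replicates 1 to 4 were 140.2, 129.6, 134 and 121 in WT M0, 111, 133, 101 and 101 in WT M1, 119, 179, 108 and 127 in WT M2, 170.5, 139, 169.9 and 124 in KO M0, 105, 113, 101 and 105 in KO M1 and 137, 125, 125 and 119 in KO M2. The equal spots show that its scale is linear intensity and that its columns were not centred or turned in sign, so neither scale, centring nor direction stays unknown, while the link of its identifiers to the probes does.

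Spots marked as outliers by the scanner software were left out, spots of a probe were averaged, and the log2 intensity of each array was taken relative to its 75th percentile. These percentiles ranged from 2291 to 4905 intensity units, a ratio of 2.14, and nonuniform spots numbered 16 to 1910 per array. Probes well above background, by the scanner software's own mark, on at least 4 of the 24 arrays were kept (39036 of 56605). Probes were assigned to genes by the names in the files, with 32994 of the gene probes (58.3%) named through a RefSeq gene table, which was used for names only, and the brightest probe stood for a gene. This gave 25955 genes, and 1985 single values were missing after outlier spots were left out.

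Differences were tested in limma 3.58.1 under R 4.3.3 (statmod 1.5.0) with 1 mean per group and moderated spread (18 residual degrees of freedom, prior degrees of freedom 1.89, median residual SD 0.332), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were KO minus WT in each state and on average over the 3 states, M1 minus M0 and M2 minus M0 in each genotype, and the difference of each response between the genotypes. Lists of genes, 29 in number, covering glucose, lipid and amino acid metabolism, stress responses, macrophage activation and identity, the lysosome, the cell cycle and markers of other cell types, were tested with camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The estimated correlation came from the model of group means without the set as a block, so differences between the sets entered it. The rotation test fry was run beside camera. Its p asks whether the genes of a list move on balance in 1 direction, and its mixed p whether they change in either direction. Neither compares a list with other genes.

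For a gene not well above background on any array of a group, the fold was computed against the floors of those arrays, the level of the dimmest signals that were still well above background, and is given as at least that size. Where only some arrays of the lower group measured a named gene well above background, each value under the floor of its array was put at the floor in the same way. Such a bound holds for the mean of a group, and the difference in a single set of arrays may lie below it. For such genes on a list, the list's median is also given with the genes at this bound. Arrays that measured a probe well above background are counted in the text where they were fewer than all.

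Genes to be named were chosen by a rule. Slc2a1 and Lyz2 were always named. For KO minus WT in a state, the 10 largest rises and 10 largest falls were named among genes that passed and whose 4 KO arrays all lay on 1 side of the 4 WT arrays (for the average, in at least 2 of the 3 states), leaving out clones, predicted loci, Riken names and bare accessions. Where fewer than 3 passed, all that did were named, with the 3 of smallest p as values only. For each activation in WT the 8 largest in each direction were named, for each difference between responses the 6 largest, and any member of a list could be named, preferably up to 4 with the smallest p. The groups, the comparisons, the lists, the naming rule and all alternatives but 5 were chosen before the data were examined; the set as a block, the fit without the 4th set, the fit without the 3 arrays with the most nonuniform spots and the macrophage identity list without Lyz2 or both lysozyme genes were added afterwards. The sets were likewise defined after the data were seen, from the slide and the position of the arrays.

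The procedure was tested on simulated data with the same groups and spread. It recovered 52.7% to 58.0% of genes given a log2 difference of 1 between a pair of groups and 81.3% to 82.7% of those given 2, and 38.3% to 40.7% and 64.3% to 65.7% for differences between responses. False calls were 3.31% to 6.14% of the calls and 0 calls had the wrong sign. The 1 list of 29 that was shifted was called, and 0 others were. Genes were simulated independently of each other and without sets or slides. These rates and the list result therefore do not cover data with such structure, which the real arrays have. Alternatives covered the scaling, the background correction, the filter, the choice of probe, blocks for slide, set and replicate number, array weights, the spread estimate, the arrays in the fit, the size of the change and the omission of each replicate. The number of arrays limits the precision of all values. Glucose uptake, protein and metabolite levels were not analysed here. A few genes that the rule names are not reported here.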

Results

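Gene expression was measured on 24 one-colour microarrays in mouse macrophages grown from bone marrow over 6 days in M-CSF (20 ng/ml), the growth factor that turns marrow precursors into macrophages. Per the labels, the cells came from mice in which Cre recombinase, inserted at the lysozyme gene Lyz2, is to remove the floxed glucose transporter gene Slc2a1 (GLUT1) in myeloid cells (KO), or from floxed controls (WT). Cells of each genotype were left unstimulated (M0), activated with 5 ng/ml lipopolysaccharide and 10 ng/ml interferon-gamma (M1), or activated with 10 ng/ml interleukin-4 (M2) for 24 h, with 4 biological replicates in each of the 6 groups. Between 55.0% and 72.6% of the gene probes were well above background on an array, and 25955 genes could be tested. The KO M1 arrays were the dimmest, with a 75th percentile of 2386 ± 115 intensity units (SD, n = 4) against 3141 ± 463 in WT M1. Values below are log2 intensities relative to each array's 75th percentile, and changes are log2 differences ± the standard error of the limma fit, with p-values adjusted by Benjamini-Hochberg and 4 arrays in each group, or 3 where the text says so. The number of arrays limits their precision.

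The arrays lay on 3 slides, and each slide held 1 complete set of the 6 groups plus 1 further pair, a WT and a KO array of 1 state. The 3 further pairs together made up a 4th set of 6 arrays, which stood apart from the other 18. In this set the Y-linked genes Ddx3y, Eif2s3y and Uty were not well above background on any array, whereas they were so on all 18 others, and Xist, the RNA of the inactive X chromosome, was well above background on 6 of 6 arrays against 2 of 18. Interferon-stimulated genes were higher in the 4th set (median log2 difference 0.94, adjusted p = 4.0e-08) and cell cycle genes lower (-0.60, adjusted p = 2.4e-05), each with adjusted p = 0.648 with an estimated correlation. Each set held every group once, so a set gave values and signs but no test of its own. The values within the sets, and the results with the set or the slide as a block in the model, are given beside each comparison.

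**Figure D1:**
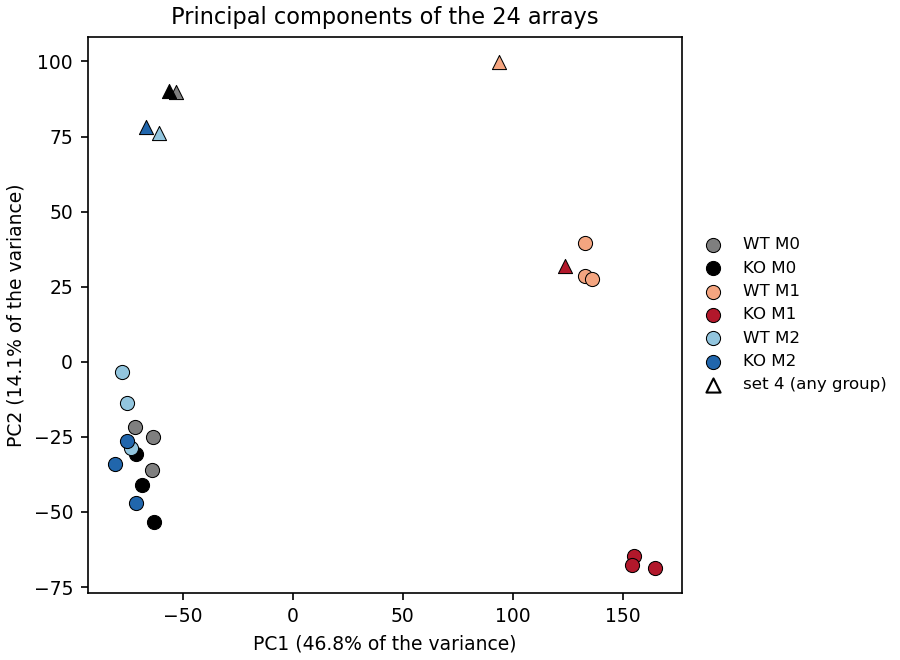
Principal components of the log2 values of the 24 arrays, 1 point per array, coloured by group, with triangles for the 4th set of arrays. The first component held 46.8% and the second 14.1% of the variance, and the M1 arrays lay apart from the M0 and M2 arrays.

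The targeted gene was examined first. Slc2a1 encodes the main glucose transporter of macrophages and was read by a single probe on chromosome 4 (mm9 118809864 to 118809923), which starts at position 2501 of the transcript. Its level was 2.80 ± 0.70 in WT M0 and 2.48 ± 0.51 in KO M0, 5.75 ± 0.50 in WT M1 and 6.00 ± 0.14 in KO M1, and 3.40 ± 0.67 in WT M2 and 3.23 ± 0.28 in KO M2 (mean ± SD, n = 4 each). In replicates 1 to 4 it was 3.76, 2.06, 2.67 and 2.72 in WT M0 and 3.1, 1.86, 2.53 and 2.42 in KO M0. In M1 it was 6.17, 5.92, 5.02 and 5.88 in WT and 6.09, 6.11, 5.81 and 5.99 in KO, and in M2 it was 4.37, 3.03, 3.30 and 2.91 in WT and 3.64, 3.07, 3.16 and 3.04 in KO. KO minus WT was -0.33 ± 0.35 in M0, 0.25 ± 0.35 in M1 and -0.18 ± 0.35 in M2 (adjusted p = 1.00, 0.584 and 1.00), and -0.08 ± 0.20 on average (adjusted p = 0.795). None of these differences passed the test. In the sets they ranged from -0.66 to -0.15 in M0, where all 4 were negative, from -0.08 to 0.79 in M1 and from -0.73 to 0.13 in M2. Which exons the Cre recombinase removed is not given in the sources used here, so the probe neither shows nor excludes the deletion. Slc2a1 itself rose with M1 activation, by 2.94 ± 0.35 in WT (adjusted p = 5.6e-07) and 3.53 ± 0.35 in KO (adjusted p = 2.4e-08), and its M2 values were 0.60 and 0.75 with adjusted p = 0.279 and 0.171.

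Lyz2, the lysozyme gene that carries the Cre insertion and so marks the genotype, was lower in every KO array than in any WT array of the same state. It fell from 7.67 ± 0.11 in WT to 5.00 ± 0.89 in KO in M0, from 8.0 ± 0.07 to 4.63 ± 0.50 in M1 and from 7.67 ± 0.13 to 3.63 ± 0.83 in M2 (mean ± SD, n = 4 each), which are differences of -2.66, -3.37 and -4.04 with adjusted p = 0.0017, 2.2e-07 and 6.4e-06. In KO replicates 1 to 4 it was 4.72, 6.33, 4.46 and 4.50 in M0, 4.77, 4.14, 5.27 and 4.33 in M1 and 3.46, 3.08, 3.12 and 4.85 in M2, and the WT values lay between 7.49 and 8.09. A second Lyz2 probe near the 5′ end of the transcript (chromosome 10, mm9 116719175 to 116719234) gave -7.38, -6.20 and -7.87. In the 4 sets the Lyz2 difference ranged from -3.36 to -1.34 in M0, from -3.79 to -2.75 in M1 and from -4.62 to -2.82 in M2, and the smallest difference in each state came from the 4th set. With M2 activation Lyz2 fell further in KO (-1.38 ± 0.37, adjusted p = 0.0167).

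**Figure D2:**
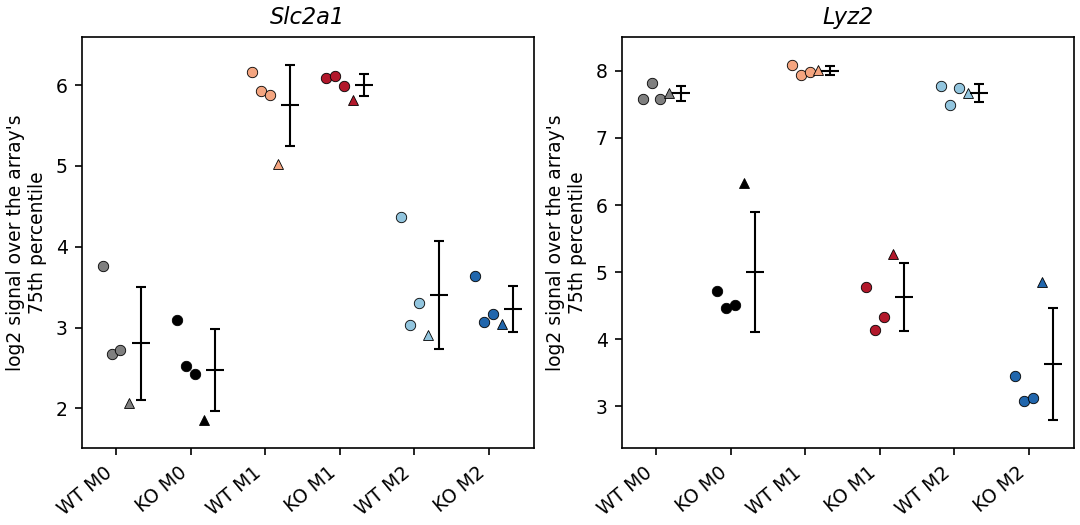
Log2 intensity of Slc2a1 and Lyz2 relative to each array's 75th percentile, 1 point per array in the 6 groups, triangles for the 4th set, and bars for the mean ± SD. Slc2a1 of KO and WT overlapped in each state, while the KO arrays lay below the WT arrays for Lyz2 in all 3.

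The comparison of KO with WT in M1 asked how macrophages labelled as carrying the Slc2a1 deletion differ after inflammatory activation, a state that relies on glucose uptake. Herpud1, a component of the endoplasmic reticulum degradation machinery, was higher in KO M1 cells and rose by 3.14 ± 0.18, and Dnajb9, a chaperone cofactor, by 2.48 ± 0.14. Derl3, which takes part in the disposal of misfolded proteins, rose 60.6-fold (5.92 ± 0.27, adjusted p = 9.3e-12). Arg1, the enzyme that splits arginine into ornithine and urea, fell from 6.10 ± 0.18 to 1.05 ± 0.62 (SD, n = 4), or 33.0-fold (limma adjusted p = 1.0e-09). Txnip, an arrestin that restrains glucose uptake and is induced by glucose, fell from 6.55 ± 0.17 to 2.98 ± 0.58, or 11.9-fold (limma adjusted p = 2.4e-09). Acadm, the medium-chain acyl-CoA dehydrogenase of fatty acid oxidation, fell by 1.34 ± 0.09. In limma, 11404 of the 25955 genes passed the adjusted p of 0.05, 5892 higher and 5512 lower in KO, and 5782 of them differed at least 2-fold. Of the called genes measured in all 4 sets, 97.3% had the same sign in each of them, a share raised by their selection on the same arrays. Over all genes it was 63.3%, against 21.0% in M0 and 19.7% in M2, and 11658 and 14065 genes passed with the slide and the set as a block. The median of all genes was 0.13 above 0 in this comparison and -0.05 with quantile normalization. The share of called genes that was higher was 51.7%, 63.8% without the filter on dim probes and 42.2% with quantile normalization.

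Among the 10 largest rises that met the naming rule was Lpar3, a receptor for lysophosphatidic acid. It was not well above background on any WT M1 array, so its change was taken against the background level of those arrays and was at least 92.1-fold. Rasd2, a small GTPase, rose 110-fold (6.78 ± 0.39, adjusted p = 4.5e-11), Kif1a, a kinesin motor of vesicle transport, 81.9-fold (6.36 ± 0.39, adjusted p = 9.2e-11), and Mreg, melanoregulin, 60.5-fold (5.92 ± 0.50, adjusted p = 7.2e-09). Rtn4r, the Nogo receptor, was at least 148-fold higher with 3 of 4 WT arrays well above background, and Efcc1 at least 74.0-fold with 1 of 4. Retnla, a secreted resistin-like protein of alternatively activated macrophages, was at least 32.9-fold higher on the mean (adjusted p = 6.8e-04, log2 difference 4.04 in the lowest set), Bex1 at least 24.3-fold and Apcdd1, an inhibitor of Wnt signalling, at least 13.3-fold. Beside Arg1 and Txnip, the largest falls were those of 1 probe of Atf7, a transcription factor of the ATF family (-5.46 ± 0.31), Cd300lb, an activating receptor of myeloid cells (-3.52 ± 0.18), Fabp7, a fatty acid binding protein (-3.54 ± 0.42), and Adora3, an adenosine receptor (-3.45 ± 0.39). The 3 other Atf7 probes well above background on all arrays were at 0.03, 0.13 and -0.11 in M1. Notch4 fell at least 13.3-fold with 3 of 4 KO arrays well above background and Rab42 at least 6.98-fold with 1 of 4, and Apof and Dnaaf4 were at least 3.57-fold and 3.13-fold lower. In the sets, the KO minus WT value of Arg1 ranged from -5.86 to -4.47 and that of Txnip from -4.11 to -2.96.

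**Figure D3:**
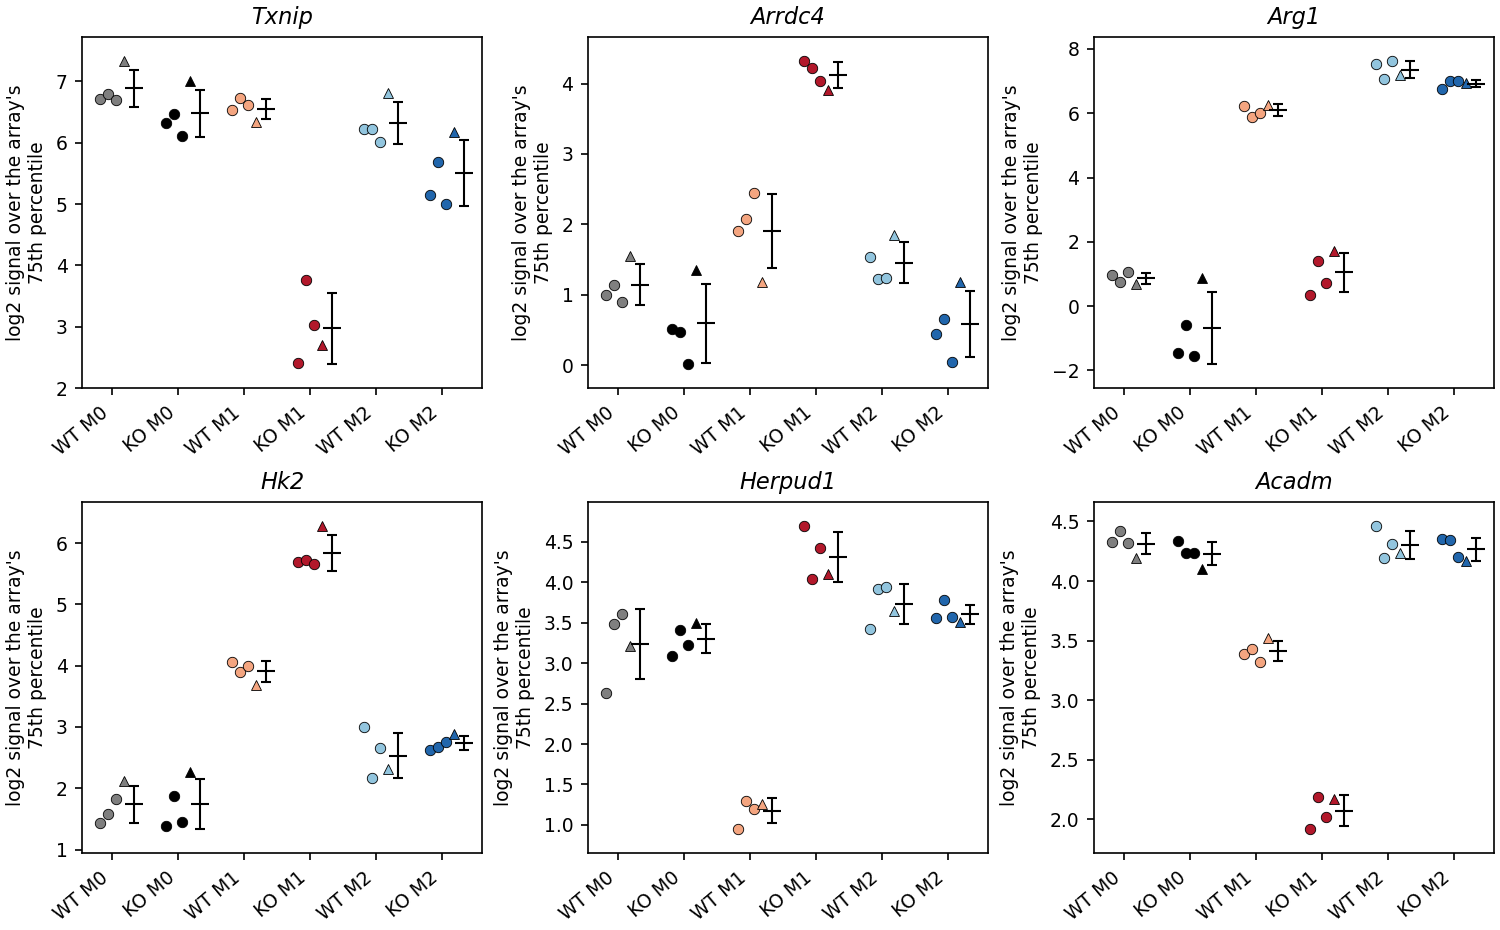
Log2 intensity relative to each array's 75th percentile of 6 genes (Txnip, Arrdc4, Arg1, Hk2, Herpud1 and Acadm) in the 6 groups, 1 dot per array, triangles for the 4th set and bars for the mean ± SD. In M1, Txnip, Arg1 and Acadm were lower in KO than in WT by 3.58, 5.04 and 1.34 (fell by these amounts on the log2 scale) and Arrdc4, Hk2 and Herpud1 were higher by 2.22, 1.93 and 3.14.

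The genes of each list fixed before the data were examined were then tested as a group, with a competitive test (camera, preset correlation of 0.01 between genes). Camera called 4 of the 29 lists in this comparison. Where no second pair of counts is given for a list, the counts adjusted over the list alone were equal to those over all genes. None of the 4 calls held when the correlation was estimated from the data, in the model without the set as a block. Over all comparisons only the interleukin-4 list in WT and in KO and the osteoclast list in WT held, all of them with M2 activation.

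Of the 19 measured genes of the endoplasmic reticulum unfolded protein response, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.25 and medians of 1.08 to 1.4 in the 4 sets. The call (adjusted p = 2.5e-09) was also made with the set and the slide as a block (3.4e-09 and 7.9e-09), against adjusted p = 0.537 with an estimated correlation. Hsp90b1, an endoplasmic reticulum chaperone, rose by 1.46 ± 0.13, and Dnajc3, an inhibitor of the kinase PERK, by 1.23 ± 0.12. Of 24 genes of the ATF4 amino acid response and serine synthesis, 15 rose and 1 fell, with a median of 1.18 and 1.06 to 1.49 in the sets. Their adjusted p was 0.00179, 0.00184 with the set and 0.00209 with the slide as a block, against adjusted p = 0.544 with an estimated correlation. Ddit4, an inhibitor of mTORC1, rose by 2.61 ± 0.24, Sesn2, a leucine sensor, by 1.52 ± 0.15, and Phgdh, the first enzyme of serine synthesis, by 3.88 ± 0.52.

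Of 24 genes of fatty acid oxidation, 14 fell and 3 rose (14 and 4 adjusted over the list alone), with a median of -0.50 and -0.59 to -0.50 in the sets. Their adjusted p was 0.00179, 0.00398 with the set and 0.00209 with the slide as a block, against adjusted p = 0.537 with an estimated correlation. Slc25a20, the mitochondrial carnitine carrier, fell by 1.39 ± 0.10, Acaa2, a thiolase, by 1.82 ± 0.14, and Cpt1a, the carnitine palmitoyltransferase at the entry of the pathway, by 1.3 ± 0.11. Of 21 genes of macrophage identity, 10 fell and 1 rose, with a median of -0.86 and -1.04 to -0.43 in the sets. Their adjusted p was 0.00621, 0.00603 with the set and 0.00656 with the slide as a block, against adjusted p = 0.537 with an estimated correlation. They included Spi1 (PU.1), the transcription factor of myeloid fate, at -1.37 ± 0.09 and C5ar1, the receptor for complement C5a, at -2.14 ± 0.18. The list holds Lyz2, which differs by the construction of the genotype. Without it 9 fell and 1 rose (median -0.65, adjusted p = 0.0174, and adjusted p = 0.544 with an estimated correlation). Without Lyz1 as well, a choice made after the values were seen like the former, 8 fell and 1 rose (median -0.43, adjusted p = 0.0425, and adjusted p = 0.703 with an estimated correlation).

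The remaining metabolic lists were not called in M1, and most held members that moved both ways. Of 23 glycolysis genes 5 rose and 6 fell (median 0.04, adjusted p = 0.937). The monocarboxylate transporter Slc16a1 rose by 2.60 ± 0.17, hexokinase Hk2 by 1.93 ± 0.21 and enolase Eno2 by 3.33 ± 0.22, while Pfkfb4, a regulator of fructose 2,6-bisphosphate, fell by 1.53 ± 0.16. Among 9 glucose transporters 1 fell, Slc2a8 by 0.40 ± 0.14, and 0 moved when adjusted over the list alone. The median of these transporters was -0.10, the mean 0.05 and the test direction down (adjusted p = 0.936). Of 11 genes of the pentose phosphate pathway 3 fell and 1 rose (median -0.19, adjusted p = 0.265), among them G6pdx, its first enzyme, at -1.62 ± 0.13. Hexosamine, glycogen and fructose genes went both ways, 6 up and 4 down of 19 (median -0.05, mean 0.00, adjusted p = 0.985). The hexosamine enzymes Uap1 and Pgm3 rose by 1.56 and 1.11.

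The 8 genes of MondoA and ChREBP glucose sensing had 2 higher and 2 lower members (4 and 3 adjusted over the list alone). Their median was 0.25, their mean -0.04 and the test direction down (adjusted p = 0.937). Txnip and its paralog Arrdc3 (-2.20 ± 0.35) fell, while their paralog Arrdc4 rose by 2.22 ± 0.28. In the tricarboxylic acid cycle 6 rose and 7 fell of 23 (7 and 7 adjusted over the list alone, median -0.06, adjusted p = 0.915). In the respiratory chain 10 rose and 6 fell of 37, with a median of 0.10 that was -0.19 with quantile normalization (adjusted p = 0.891). Of 17 glutamine and amino acid genes 7 rose and 5 fell (median 0.11, adjusted p = 0.891), with the large neutral amino acid transporter Slc7a5 up by 2.22 ± 0.31.

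In cholesterol synthesis 7 rose and 9 fell of 23 (9 and 9 adjusted over the list alone, median 0.15, adjusted p = 0.937). Its enzyme Mvd rose by 2.43 ± 0.19 and Ebp fell by 0.70 ± 0.09. In the LXR and fatty acid synthesis list 4 rose and 5 fell of 20 (median 0.29, 0.13 with genes at their bound, adjusted p = 0.980), and fatty acid synthase Fasn rose by 2.12 ± 0.17. The HIF-1 list had 7 higher and 7 lower of 20, with a median of -0.07, a mean of 0.03 and a test direction of down (adjusted p = 0.937). The growth factor Vegfa rose by 2.59 ± 0.43 and carbonic anhydrase Car9 fell by 1.68 ± 0.18. The NRF2 list had 5 higher and 2 lower of 21 (median 0.14, adjusted p = 0.936), with the peroxidase Gpx1 at -1.38 ± 0.17.

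Among the activation lists, 8 of 34 inflammatory genes were higher and 3 lower in KO M1 (7 and 3 adjusted over the list alone). Their median was 0.25, and -0.01 with quantile normalization (adjusted p = 0.915). Il12b, the shared subunit of interleukin-12 and interleukin-23, rose by 4.03 ± 0.48 (3 KO arrays with a value) and the Toll-like receptor Tlr2 by 1.67 ± 0.26, while the co-stimulatory molecule Cd80 fell by 1.43 ± 0.17. Of 28 interferon-stimulated genes 0 rose and 2 fell (0 and 1 adjusted over the list alone, median -0.29, adjusted p = 0.516). Of 24 antigen presentation genes 4 rose and 1 fell, with a median of 0.11 that was -0.18 with quantile normalization (adjusted p = 0.937). The class II regulator Ciita rose by 1.94 ± 0.36. Interleukin-4 genes included 12 that rose and 5 that fell of 28 (adjusted p = 0.909). Their median was 0.37, 0.06 with genes at their bound and -0.12 with quantile normalization, and the mannose receptor Mrc1 rose by 2.64 ± 0.43 beside the fall of Arg1.

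Of 26 uptake and scavenger genes 10 fell and 6 rose (11 and 6 adjusted over the list alone). Their median was -0.29, their mean 0.10 and the test direction down (adjusted p = 0.597), with the receptor Lrp1 at -1.53 ± 0.18. Of 27 lysosomal genes 11 rose and 3 fell (12 and 4 adjusted over the list alone, median 0.27, adjusted p = 0.0987), and the proton pump subunit Atp6v0d2 rose by 3.93 ± 0.23. Of 32 cell cycle genes 10 rose and 4 fell (median 0.83, 0.60 with genes at their bound, adjusted p = 0.268). The proliferation marker Mki67 rose by 2.94 ± 0.30 and the replication factor Mcm2 by 2.62 ± 0.40.

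The lists of other cell types gave no call in M1. Of 15 neutrophil genes 4 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 1.22 and -0.08 to 3.06 in the sets (adjusted p = 0.516). The neutrophil genes Camp and Ly6g were at 2.28 ± 0.77 and -2.75 ± 0.70. Of 10 dendritic cell genes 4 rose and 2 fell (median 0.66, adjusted p = 0.909). Of 13 lymphocyte genes 4 rose, the kinase Lck by 1.68 ± 0.23, and 1 fell (median 0.34, 0.27 with genes at their bound, adjusted p = 0.597). Of 10 erythroid and mast cell genes 3 rose and 0 fell (median 1.49, 0.61 with genes at their bound, adjusted p = 0.268). Of 13 stromal genes 3 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.74, 0.50 with genes at their bound, adjusted p = 0.597). Of 12 osteoclast genes 3 rose and 2 fell (median 0.11, adjusted p = 0.891), among them Atp6v0d2 and the integrin Itgb3, which rose by 4.21 ± 0.31.

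**Figure D4:**
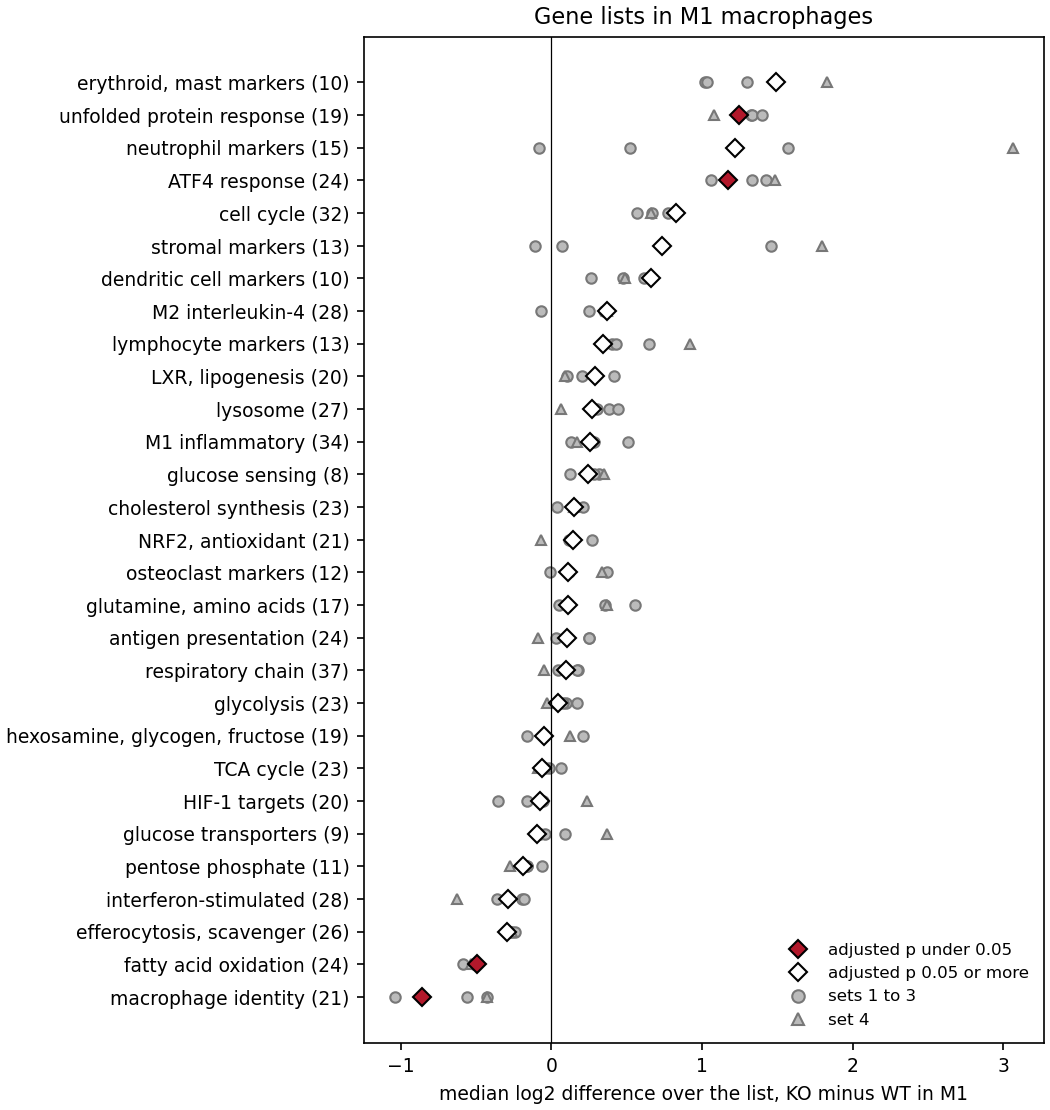
KO minus WT in M1 (log2) for the 29 gene lists, with the number of measured genes in brackets. Diamonds are the median over each list in the fit, red where camera's adjusted p was under 0.05 with the preset correlation, and grey circles and triangles are the medians in sets 1 to 3 and in the 4th set; the unfolded protein response lay at 1.25 and fatty acid oxidation at -0.50.

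In unstimulated cells the comparison asked how KO differed from WT without activation, and few genes differed. KO minus WT also carries the Cre insertion at Lyz2, which no comparison here separates from a loss of Slc2a1. Beside Lyz2, Atf7 fell 95.8-fold at its probe (-6.58 ± 0.31, adjusted p = 9.6e-11), Hhipl1 fell 11.1-fold (-3.47 ± 0.21, adjusted p = 4.2e-09), and Platr9, a noncoding RNA, by 3.06 ± 0.35 (adjusted p = 1.3e-04). Scn4b, a sodium channel subunit, the olfactory receptor genes Olfr706 and Olfr1466 and Fbll1 were lower by 1.93, 1.73, 1.38 and 1.70 (these are falls on the log2 scale). Their KO arrays all lay below the WT arrays. The Atf7 fall was seen at 1 probe, and the other 3 probes of the gene that were well above background on all arrays differed by at most 0.137 on average over the states. In all, limma called 14 genes, 2 higher and 12 lower, with 822 at an unadjusted p under 0.05, fewer than chance gives. The higher ones, outside the naming rule and chosen after their values were seen, were B230217O12Rik (0.73 ± 0.10) and ENSMUST00000119478 (0.98 ± 0.14, 3 WT arrays with a value). All 13 of the called genes measured in the 4 sets kept their sign in each (21.0% of all genes did), and 21 and 20 genes passed with the slide and the set as a block. Retnla did not pass (adjusted p = 0.207), its KO and WT arrays overlapped and the difference was 0.15 in 1 of the 4 sets, so no size is given. Tspoap1, at 1.85 ± 0.43 (adjusted p = 0.286), and Tppp3, at 1.14 ± 0.26 (adjusted p = 0.288), did not pass either.

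Camera called 9 lists in M0, of which 8 were lower in KO, and no member of them apart from Lyz2 passed over all genes. Glycolysis genes had a median of -0.22 (adjusted p = 1.8e-04), the tricarboxylic acid cycle -0.12 (adjusted p = 1.8e-04), and the respiratory chain -0.09 (adjusted p = 1.6e-07, 1 member lower adjusted over the list alone). Fatty acid oxidation was at -0.09 (adjusted p = 0.0132), HIF-1 targets at -0.17 (adjusted p = 0.0105) and the lysosome at -0.11 (adjusted p = 0.00163). Macrophage identity was at -0.11 (adjusted p = 5.9e-04, 1 lower over all genes, Lyz2, and 2 adjusted over the list alone). Each of these 7 lists gave adjusted p = 0.425 with an estimated correlation. Without Lyz2 the identity list had adjusted p = 0.0159 (and adjusted p = 0.425 with an estimated correlation), and without Lyz1 as well it was not called (adjusted p = 0.123). The unfolded protein response had a median of -0.13 (adjusted p = 0.021, and adjusted p = 0.717 with an estimated correlation). Inflammatory genes were higher at 0.12 (adjusted p = 0.0171, and adjusted p = 0.582 with an estimated correlation). All 9 calls were made with the slide and with the set as a block. Only glycolysis, the tricarboxylic acid cycle and the respiratory chain had medians below 0 in all 4 sets (-0.30 to -0.11, -0.16 to -0.05 and -0.17 to -0.03). With quantile normalization 2 of the 9 calls were made, glycolysis and the inflammatory list (adjusted p = 0.0238 each).

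After interleukin-4, the comparison of KO with WT asked the same in alternatively activated cells. Atf7 at the same probe (-6.42 ± 0.31, adjusted p = 1.5e-10), Hhipl1 (at least 4.78-fold, with 1 of 4 KO arrays well above background) and Platr9 (at least 3.05-fold, 1 of 4) were lower again, and Lyz1, the neighbouring lysozyme gene, fell 5.01-fold (-2.33 ± 0.26, adjusted p = 1.2e-04) at a probe whose smallest difference came from the same set of arrays as that of Lyz2 in 3 of 3 states. Tspoap1 rose 6.29-fold (2.65 ± 0.43, adjusted p = 0.0146), Poln, a DNA polymerase, 2.73-fold (1.45 ± 0.24, adjusted p = 0.0236), and Cntd1 at least 2.75-fold, while AK084221, chosen after its values were seen, was at least 1.33-fold higher and well above background on 2 of 4 KO M2 arrays. Limma called 11 genes, 4 higher and 7 lower, with 1150 at an unadjusted p under 0.05, fewer than chance gives. All 11 kept their sign in the 4 sets, as did 19.7% of all genes. With the slide as a block 10 genes passed, with the set as a block 28 (18 higher and 10 lower), and without the 4th set 60 (50 higher and 10 lower), so the balance of directions turned.

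The interleukin-4 genes themselves were not called in this comparison. Camera called 7 lists without any member that passed over all genes. The respiratory chain was lower (median -0.10, adjusted p = 4.4e-08), as were the unfolded protein response (-0.17, adjusted p = 1.4e-05), the tricarboxylic acid cycle (-0.12, adjusted p = 1.6e-04) and fatty acid oxidation (-0.06, adjusted p = 0.012). The ATF4 response (0.34, adjusted p = 0.00647) and the LXR list (0.17, adjusted p = 0.0319) were higher. Each of these 6 gave adjusted p = 0.472 with an estimated correlation. Interferon-stimulated genes were lower (-0.19, adjusted p = 0.012, and adjusted p = 0.784 with an estimated correlation). Adjusted over the list alone, Scd1, a fatty acid desaturase, passed in the LXR list (adjusted p = 0.504 over all genes, well above background on 3 of 4 KO and 0 of 4 WT arrays) and Vldlr in the ATF4 list (1.23, adjusted p = 0.483 over all genes). All 7 calls were made with the slide and the set as a block, and 5 had medians of 1 sign in all 4 sets. The exceptions were the respiratory chain (-0.28 to 0.04) and fatty acid oxidation (-0.19 to 0.05). With quantile normalization the calls of fatty acid oxidation and of the interferon list were lost (adjusted p = 0.0702 and 0.0669).

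The average of KO minus WT over the 3 states was carried largely by M1, since 14 and 11 genes were called in M0 and M2 against 11404 in M1. In this average Cdkn1c, an inhibitor of cyclin-dependent kinases, rose by 2.18 ± 0.26 (adjusted p = 3.6e-06), Tmem266 by 1.91 ± 0.14 (3 of 4 arrays well above background in each M2 group and 3 WT M2 arrays with a value), the homeobox repressor Tgif2 by 1.82 ± 0.25 and the coactivator Cited4 by 1.63 ± 0.15. Lpar3, Apcdd1, Larp6, Scd1 and Adamts15 were among the 10 largest rises too, but were not well above background on any WT M1 array, so no size is given. Nor is it for Il12b (adjusted p = 1.6e-06), which was so on 2 of 4 WT M2 arrays. Atf7 at 1 probe (-6.15 ± 0.18), Lyz2 (-3.36 ± 0.21), Arg1 (-2.34 ± 0.21), Prdm16, a zinc finger regulator (-1.89 ± 0.26), and Lyz1 (-1.86 ± 0.15) fell. So did Hhipl1 (at 1 probe), Platr9, Olfr706 and Scn4b. These genes were well above background on 1, 1, 2 and 0 of 4 KO M2 arrays, so no size is given. Limma called 7441 genes, 3770 higher and 3671 lower, of which 603 differed at least 2-fold, and 97.2% of those measured in the 4 sets kept their sign in each, against 53.3% of all genes. The share that rose was 50.7%, 41.4% with quantile normalization and 59.1% without the 4th set. With the slide as a block 7655 passed, and with the set 10444.

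The 4 lists called in M1 were called on average too, although the unfolded protein response was lower in M0 and M2, so its rise on average came from M1. The ATF4 response rose (13 of 24 higher, 1 lower, 14 and 1 adjusted over the list alone, median 0.56, adjusted p = 4.2e-04 and adjusted p = 0.515 with an estimated correlation). So did the unfolded protein response (12 and 0 of 19, 14 and 0 adjusted over the list alone, median 0.34, adjusted p = 2.3e-05 and adjusted p = 0.558 with an estimated correlation). Fatty acid oxidation (14 of 24 lower, 1 higher, 16 and 3 adjusted over the list alone, median -0.21, adjusted p = 1.3e-04) and macrophage identity (6 of 21 lower, 0 higher, median -0.21, adjusted p = 9.9e-04) fell. Each gave adjusted p = 0.424 with an estimated correlation. Without Lyz2 the identity list had adjusted p = 0.00759 (and adjusted p = 0.532 with an estimated correlation), and without Lyz1 as well adjusted p = 0.0412 (and adjusted p = 0.558 with an estimated correlation). All 4 calls were made with the slide and the set as a block, and their medians had 1 sign in the 4 sets.

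The effect of M1 activation in WT cells gave the background against which the genotypes are compared. Among the 8 largest rises, Iigp1, an interferon-induced GTPase of defence against intracellular microbes, rose 1496-fold (10.55 ± 1.04, adjusted p = 5.4e-08) and the protease inhibitor Serpina3g 1347-fold (10.40 ± 0.78, adjusted p = 1.3e-09). Cxcl9, Gbp4 (3 M1 arrays with a value) and Serpina3f, well above background on 1 of 4 M0 arrays, rose at least 4982-fold, 2344-fold and 586-fold on the mean, with log2 differences of 9.14 for Cxcl9 and 8.01 for Serpina3f in their lowest sets. Ptgs2, the cyclooxygenase of prostaglandin synthesis, and Clic5, so on 3 of 4, rose at least 1038-fold and 1435-fold, and Gbp2b at least 386-fold. Among the 8 largest falls, Ccna2, cyclin A, fell 397-fold (-8.63 ± 0.39, adjusted p = 1.2e-12), Cenpf at least 247-fold, Aspm at least 225-fold, Pbk at least 205-fold, Ska1 at least 101-fold and Kif4 at least 89.7-fold. Pimreg fell at least 582-fold, and the transporter Slco2b1 fell 314-fold (-8.30 ± 0.60). Limma called 12417 genes, 6735 higher and 5682 lower, with 6260 of them at least 2-fold, and the share that rose was 54.2%, or 49.5% with quantile normalization. Of those measured in the 4 sets, 96.0% kept their sign, against 62.2% of all genes, and 12614 and 14341 passed with the slide and the set as a block.

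Camera called 11 lists with M1 activation in WT, 7 of them up. All 28 interferon-stimulated genes rose (median 4.48, adjusted p = 2.0e-14), as did all 24 antigen presentation genes (2.46, adjusted p = 1.8e-14), with the peptide transporter subunit Tap1 at 3.69 ± 0.17. Of 34 inflammatory genes 26 rose and 2 fell (27 and 2 adjusted over the list alone, 4.97, adjusted p = 1.6e-08). The nitric oxide synthase Nos2 rose by 10.17 ± 0.45 and the co-stimulatory receptor Cd40 by 5.56 ± 0.24. Of 23 glycolysis genes 15 rose and 3 fell (0.82, adjusted p = 4.7e-04), with the glycolytic regulator Pfkfb3 at 3.78 ± 0.27 and the lactate exporter Slc16a3 at 3.53 ± 0.28. Of 20 HIF-1 targets 14 rose and 1 fell, the related factor Epas1 at -4.22 ± 0.30 (15 and 1 adjusted over the list alone, 1.08, adjusted p = 0.00101). Dendritic cell genes rose in 6 of 10 cases (1.42, adjusted p = 0.0256). Cell cycle genes fell in 26 of 32 cases and rose in 3 (27 and 3 adjusted over the list alone, -3.76, adjusted p = 2.0e-14). Cholesterol synthesis genes fell in 15 of 23 cases and rose in 2 (-0.87, adjusted p = 9.4e-06), with the sterol carrier Stard4 at -3.22 ± 0.16 and the isomerase Idi1 at -3.17 ± 0.19. These 8 lists each gave adjusted p = 0.317 with an estimated correlation.

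NRF2 genes also rose in WT (12 of 21, 2 fell, 13 and 3 adjusted over the list alone, 0.94, adjusted p = 0.019, and adjusted p = 0.744 with an estimated correlation). This call was lost with quantile normalization (adjusted p = 0.132). Uptake and scavenger genes fell (11 of 26, 5 rose, -0.32, adjusted p = 0.031, and adjusted p = 0.342 with an estimated correlation). Among them were the phagocytic receptor Trem2 at -1.76 ± 0.11 and the bridging ligand Gas6 at -4.11 ± 0.28. Neutrophil genes fell (9 of 15, 1 rose, 10 and 1 adjusted over the list alone, -2.65, adjusted p = 0.0256, and adjusted p = 0.744 with an estimated correlation). The granule gene Ltf was at -3.99 ± 0.85 and Ly6g, which rose, at 5.21 ± 0.70. All 11 calls were made with the slide and the set as a block and had medians of 1 sign in the 4 sets.

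In KO cells M1 activation raised and lowered many of the same genes. Hk2 rose by 4.09 ± 0.21, Cd40 by 6.36 ± 0.24 and Nos2 by 9.44 ± 0.45. Limma called 14646 genes, 8545 higher and 6101 lower, 8106 of them at least 2-fold, and 96.3% of those measured in the 4 sets kept their sign, against 67.1% of all genes (14906 and 16346 with the slide and the set as a block). The median of all genes was 0.25, and 0.04 with quantile normalization, which brought the share that rose from 58.3% to 47.3%; without the filter on dim probes it was 69.9%. Between the genotypes, which shared no arrays in these contrasts, 9551 genes were called in both, 4748 rising in both against 2217 expected from the counts alone and 3529 falling in both against 1336. Thus 8277 moved in the same direction and the remainder in opposite directions.

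In KO, 14 lists were called, 10 up. All 28 interferon-stimulated genes rose (median 4.01, adjusted p = 8.8e-10, and adjusted p = 0.383 with an estimated correlation). All 24 antigen presentation genes rose (2.77, adjusted p = 5.8e-11), and of 34 inflammatory genes 27 rose and 1 fell (29 and 1 adjusted over the list alone, 4.27, adjusted p = 8.1e-07). All 19 genes of the unfolded protein response rose (1.55, adjusted p = 8.5e-08), with the chaperone Hyou1 at 3.22 ± 0.24. Of 24 genes of the ATF4 response 17 rose and 3 fell (1.91, 1.75 with genes at their bound, adjusted p = 4.1e-04), with the cystine transporter Slc7a11 at 6.65 ± 0.52. Glycolysis rose in 18 of 23 cases and fell in 5 (1.3, adjusted p = 4.3e-04), and dendritic genes rose in 7 of 10 (1.51, adjusted p = 0.0224). Fatty acid oxidation fell in 14 of 24 cases and rose in 5 (-0.46, adjusted p = 0.00161). Its dehydrogenase Acadm was at -2.15 ± 0.09 and Acsl1, a long-chain acyl-CoA synthetase that rose, at 4.62 ± 0.17. Uptake and scavenger genes fell in 15 of 26 cases and rose in 7 (-0.42, adjusted p = 0.017). Apart from the interferon list, each of these gave adjusted p = 0.316 with an estimated correlation.

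HIF-1 targets rose in KO (13 of 20, 3 fell, 1.37, adjusted p = 0.00765, and adjusted p = 0.342 with an estimated correlation), with Vegfa at 5.59 ± 0.43. Cholesterol synthesis fell (16 of 23, 3 rose, -0.86, adjusted p = 3.5e-04, and adjusted p = 0.383 with an estimated correlation), although Mvd rose by 2.45 ± 0.19. The cell cycle fell (25 of 32, 2 rose, -3.55, adjusted p = 9.2e-11, and adjusted p = 0.362 with an estimated correlation). Lysosomal genes rose (21 of 27, 5 fell, 0.67, adjusted p = 0.0116, and adjusted p = 0.420 with an estimated correlation). So did NRF2 genes (15 of 21, 2 fell, 15 and 3 adjusted over the list alone, 0.90, adjusted p = 0.020, and adjusted p = 0.564 with an estimated correlation). Neither of these calls was made with quantile normalization, where the lysosomal median was -0.06 (adjusted p = 0.867 and 0.374). All 14 calls were made with the slide and the set as a block, with medians of 1 sign in the 4 sets.

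The test of the difference between the genotypes in their M1 response, KO minus WT, gave 7739 genes, 3893 with a larger or more positive change in KO and 3846 with a smaller or more negative one (4644 at least 2-fold). Derl3 (6.15 ± 0.38, adjusted p = 4.5e-09) and Rasd2 (6.66 ± 0.55, adjusted p = 2.9e-08) were among the 6 largest positive values. The others, Lpar3, Rtn4r, Efcc1 and the dopamine receptor Drd1, were well above background on all 4 KO M1 arrays but on 0, 1, 1 and 1 of 4 WT M0 arrays, so no size is given. The calcium channel gene Calhm2 (-3.40 ± 0.31, adjusted p = 9.1e-08), Arg1 (-3.5 ± 0.53, adjusted p = 2.9e-05) and the Toll-like receptor Tlr12 (-3.87 ± 1.1, 3 of 4 WT M0 arrays well above background) were among the 6 most negative. The phospholipase Pla2g3, Gbp2b and Dnaaf4 were the others, each not well above background on any array of at least 1 group, so no size is given. Txnip (-3.17 ± 0.40) and Arrdc4 (2.77 ± 0.40) parted here as well, and Hk2 was at 1.93 ± 0.29. Of the called genes measured in the 4 sets, 98.6% kept their sign, against 55.1% of all genes, and 7954 and 9984 passed with the slide and the set as a block. The share of positive values was 50.3%, 63.1% without the filter on dim probes and 41.9% with quantile normalization, and the median of all genes moved from 0.12 to -0.03 with quantile normalization.

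Camera called 4 lists for this difference. The unfolded protein response was higher (17 of 19, 0 lower, 19 and 0 adjusted over the list alone, median 1.39, adjusted p = 3.1e-11, and adjusted p = 0.604 with an estimated correlation), and its median was 1.00 to 1.65 in the sets. The ATF4 response was higher (10 of 24, 1 lower, 12 and 1 adjusted over the list alone, 1.22, adjusted p = 0.00568), and fatty acid oxidation lower (12 of 24, 3 higher, 13 and 3 adjusted over the list alone, -0.46, adjusted p = 0.00568). The lysosome was higher (12 of 27, 2 lower, 12 and 3 adjusted over the list alone, 0.35, adjusted p = 0.0148), with the calcium channel Mcoln1 at 1.28 ± 0.12. Each of these 3 lists gave adjusted p = 0.903 with an estimated correlation. Their medians ranged from 0.98 to 1.54, from -0.55 to -0.37 and from 0.16 to 0.70 in the sets. All 4 calls were made with the slide and the set as a block, and the lysosomal call was lost with quantile normalization (median 0.02, adjusted p = 0.531).

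After interleukin-4 in WT cells Flt1, a receptor for vascular endothelial growth factor, rose 153-fold (7.25 ± 0.43, adjusted p = 2.7e-09), Pdcd1lg2, the ligand PD-L2, 140-fold (7.13 ± 0.49, adjusted p = 1.5e-08) and the ribonuclease Rnase2a 106-fold (6.73 ± 0.93). These 3 genes had a value on 3 WT M2 arrays each after outlier spots were left out. Retnla (adjusted p = 7.2e-06), well above background on 3 of 4 M0 arrays, rose by 6.57 to 15.78 in the sets, so no single size is given. The cytokine receptor Il31ra, well above background on 2 of 4 M0 arrays, rose at least 173-fold, and Msx3, Cdh1 and Edn1 rose at least 47.9-fold, 40.6-fold and 39.2-fold on the mean, Edn1 by 3.41 (log2) in its lowest set. Cx3cr1, the fractalkine receptor, fell 61.9-fold (-5.95 ± 0.74, adjusted p = 1.0e-05), Gpr162 22.1-fold (-4.47 ± 0.43) and the Fc receptor-like Fcrl1 21.2-fold (-4.41 ± 0.24), Gpr82 at least 6.39-fold and Dkk2 at least 5.74-fold, and Adgre4, Ifit3b and Itga8, well above background on 3, 2 and 2 of 4 M2 arrays, at least 20.3-fold, 11.1-fold and 8.58-fold, Ifit3b by 1.43 (log2) in the set with the smallest fall. Limma called 3914 genes, 1624 higher and 2290 lower, 1629 of them at least 2-fold. Of those measured in the 4 sets, 98.9% kept their sign, against 46.8% of all genes, and 4193 genes passed with the slide, 6519 with the set as a block and 5872 without the 4th set. The share that rose was 41.5%, 52.3% without the 3 arrays with the most nonuniform spots, 38.2% with the set as a block and 33.3% without the 4th set.

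Camera called 10 lists with interleukin-4 in WT. The interleukin-4 genes rose (24 of 28, 1 fell, 25 and 1 adjusted over the list alone, adjusted p = 3.35e-35, and adjusted p = 3.2e-07 with an estimated correlation). Their median was 3.89, and 3.5 with genes at their bound, with Arg1 at 6.49 ± 0.37, the suppressor of cytokine signalling Socs1 at 6.07 ± 0.26 and the transcription factor Irf4 at 5.15 ± 0.23. Osteoclast genes rose (5 of 12, 1 fell, 6 and 1 adjusted over the list alone, 1.03, adjusted p = 0.00112, and adjusted p = 0.0204 with an estimated correlation). The fusion gene Ocstamp was at 4.95 ± 0.58 and Nfatc1, the osteoclast transcription factor, at -0.81 ± 0.16. The respiratory chain rose (26 of 37, 32 adjusted over the list alone, 0.39, adjusted p = 5.25e-20), as did the unfolded protein response (13 of 19, 16 adjusted over the list alone, 0.69, adjusted p = 5.9e-15), with the disulfide isomerase Pdia4 at 2.18 ± 0.17. Cholesterol synthesis rose too (13 of 23, 18 adjusted over the list alone, 0.64, adjusted p = 6.6e-12). These 3 lists had 0 members that fell, and each gave adjusted p = 0.0845 with an estimated correlation.

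The tricarboxylic acid cycle rose (13 of 23, 15 adjusted over the list alone, 0.35, adjusted p = 3.4e-10, and adjusted p = 0.129 with an estimated correlation). Fatty acid oxidation rose (5 of 24, 8 adjusted over the list alone, 0.22, adjusted p = 7.5e-04, and adjusted p = 0.243 with an estimated correlation), with the coactivator Ppargc1b at 3.26 ± 0.26. Antigen presentation rose (7 of 24, 1 fell, 9 and 2 adjusted over the list alone, 0.32, adjusted p = 2.6e-04) and NRF2 genes fell (6 of 21, -0.35, adjusted p = 0.0129). Each of these gave adjusted p = 0.719 with an estimated correlation. Interferon-stimulated genes fell (8 of 28, 11 lower and 1 higher adjusted over the list alone, -0.86, adjusted p = 9.5e-04, and adjusted p = 0.780 with an estimated correlation). All 10 calls were made with the slide and the set as a block, with medians of 1 sign in the 4 sets.

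In KO cells interleukin-4 gave 3371 genes in limma, 1765 higher and 1606 lower, with 1383 at least 2-fold, and Arg1 rose by 7.60 ± 0.37, Socs1 by 5.60 ± 0.26, Irf4 by 4.95 ± 0.23 and Flt1 by 6.77 ± 0.43 (3 KO M0 arrays with a value). Of those measured in the 4 sets, 98.7% kept their sign, against 48.1% of all genes, and 3536 and 5913 passed with the slide and the set as a block. The share that rose was 52.4%, 47.9% with scaling on the median of bright probes, and 72.7% of 6360 genes without the filter on dim probes. The genotypes had 2682 called genes in common and all of them moved in 1 direction, 1350 up against 110 expected from the counts and 1332 down against 142.

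The called lists in KO were 11, 10 of them up. Interleukin-4 genes rose (24 of 28, 1 fell, 25 and 1 adjusted over the list alone, adjusted p = 7.65e-34, and adjusted p = 4.3e-07 with an estimated correlation), with a median of 3.68, and 3.46 with genes at their bound. Osteoclast genes rose (5 of 12, 1 fell, 7 and 2 adjusted over the list alone, 1.11, adjusted p = 0.00605, and adjusted p = 0.0609 with an estimated correlation). The respiratory chain (23 of 37, 32 adjusted over the list alone, 0.38, adjusted p = 1.4e-19) and the unfolded protein response (14 of 19, 15 adjusted over the list alone, 0.66, adjusted p = 4.1e-13) rose. Each gave adjusted p = 0.0901 with an estimated correlation. Cholesterol synthesis rose (17 of 23, 20 adjusted over the list alone, 0.72, adjusted p = 8.8e-15, and adjusted p = 0.0668 with an estimated correlation). The tricarboxylic acid cycle rose (13 of 23, 17 adjusted over the list alone, 0.40, adjusted p = 4.1e-10, and adjusted p = 0.132 with an estimated correlation). Fatty acid oxidation rose (7 of 24, 9 adjusted over the list alone, 0.20, adjusted p = 4.6e-04, and adjusted p = 0.221 with an estimated correlation).

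Glycolysis rose with interleukin-4 in KO (7 of 23, 2 fell, 11 and 4 adjusted over the list alone, 0.25, adjusted p = 0.0158, and adjusted p = 0.629 with an estimated correlation), with the phosphofructokinase Pfkp at 1.66 ± 0.22. So did the lysosome (4 of 27, 1 fell, 5 and 1 adjusted over the list alone, 0.12, adjusted p = 0.0105, and adjusted p = 0.629 with an estimated correlation). With quantile normalization neither was called (adjusted p = 0.320 and 0.813) and the lysosomal median was -0.06. Antigen presentation rose (8 of 24, 8 and 2 adjusted over the list alone, 0.24, adjusted p = 2.3e-04, and adjusted p = 0.680 with an estimated correlation). Interferon-stimulated genes fell (8 of 28, 14 lower and 1 higher adjusted over the list alone, -1.02, adjusted p = 2.2e-05, and adjusted p = 0.694 with an estimated correlation). All 11 calls were made with the slide and the set as a block, with medians of 1 sign in the 4 sets.

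Whether the response to interleukin-4 differed between the genotypes was tested directly, and limma called 0 genes and camera 0 lists, with 256 genes at an unadjusted p under 0.05. Among the smallest p-values was that of Cd247, a T cell receptor subunit (-1.01 ± 0.28, adjusted p = 1.00). Olfr945, Olfr1101 and Olfr10 also had small ones but were not well above background on any array of at least 1 group, so no size is given. With independent genes and no sets, a simulation of this contrast recovered 64.3% of genes given a log2 difference of 2, so smaller ones may have been missed.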

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

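The tests of the 3 patterns below were chosen after the result was seen, apart from the test of Lyz1 hybridisation, the test of sex-linked genes alone and the counts of other splits of the samples, which were planned.

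KO and WT differed in far more genes in M1 than in M0 or M2, and the test of the difference in M1 response gave 7739 genes, with list medians of 1.39 for the unfolded protein response, 1.22 for the ATF4 response, 0.35 for the lysosome and -0.46 for fatty acid oxidation. The tables argue against the scaling of the dimmer KO M1 arrays as the cause, since 11345 genes were called in M1 with quantile normalization, and against probes near background, since 55.6% of the 17367 genes well above background on all arrays were called. Set and slide effects cancel in KO minus WT, as each held both genotypes, and were not tested. Of all genes, 63.3% had the same sign in all 4 sets in M1, against 21.0% in M0 and 19.7% in M2. This share replaced, after its result was known, that of the called genes (97.3%), picked on the same arrays. A weaker activation of the KO cells cannot be the whole cause: dividing the WT M1 arrays so that the response and the difference shared none of them, at most 70.1% of genes called in both went in opposite directions, and the remainder changed further in the direction of activation. A different M1 response of the cells labelled KO is a candidate explanation. Array position, fixed by group in sets 1 to 3, was not tested, and weaker activation stays open for a part of the genes. KO also carries the Cre insertion and the loss of Lyz2, which no comparison here separates from a loss of Slc2a1.

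In each of the 3 states 6 genes were lower in KO, among them Lyz2, Atf7, Hhipl1, Platr9 and the transcript AK042874, with -3.47 for Hhipl1 in M0, for example. For these genes a chromosome segment carried along with the Cre met a value against it, since 0 of the other 5 genes lay close to Lyz2 or Slc2a1: the nearest case, Platr9, starts at 34857133 of chromosome 4 (mm9) and the Slc2a1 probe at 118809864. The controls were floxed too, so the test of the floxed locus was fixed by the design and is not counted. Lyz1, next to Lyz2, was not among these genes, as it was not called in M0. For Atf7 a loss at the position of 1 probe, such as a strain difference or a transcript form, is a candidate explanation, because the 3 other Atf7 probes well above background on all arrays differed by at most 0.137 on average over the states. A further Atf7 probe, well above background on 6 arrays, gave 0.86. Lyz1, the neighbour of Lyz2, may owe its lower signal to Lyz2 transcripts that bind its probe in WT cells: in 3 of 3 states the set with the smallest Lyz2 difference also had the smallest Lyz1 difference, while a true fall of Lyz1 stays open. No biological explanation was tested for Hhipl1, Platr9 and AK042874.

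The 4th set of 6 arrays stood apart from the other 18, with 9537 genes that differed, 3732 higher and 5805 lower. Animals of another sex are a candidate explanation for a part of this, since 3 of 4 Y-linked genes were not well above background in the set and were so on all other arrays. The slide does not account for it, since the deviations of the 6 arrays had a mean correlation of -0.321 over genes with the other arrays of their slide and 0.596 with each other. Sex-linked genes alone do not either, since 3.77% of the genes that differed lay on chromosome X or Y. Age, litter or a separate experiment of these animals stays open and untested, and as each group has 1 array in the set, the comparisons hold it in balance.

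Among 78 groups of 4 arrays examined, 10 held an array far from the other 3, where chance gives about 1 in 20, and 9 of the 10 belonged to the 4th set. Lyz2 was 6.33 in KO M0 replicate 2 against 4.46 to 4.72 in the others of its group, and Lyz1 was 4.58 in the same array against 3.24 to 3.42. Lyz1 was also 3.73 in KO M1 replicate 3 against 3.24 to 3.32 and 3.51 in KO M2 replicate 4 against 2.29 to 2.42. Atf7 was -1.61 in KO M1 replicate 3 against -2.35 to -2.30, and Hk2 was 6.28 in that array against 5.66 to 5.72. Txnip was 7.33 in WT M0 replicate 2 against 6.70 to 6.79, and Mki67 was 4.29 in that array against 5.40 to 5.59 and 4.68 in WT M2 replicate 4 against 5.15 to 5.24. The exception to the 4th set was Retnla, 7.84 in KO M2 replicate 2 against 7.46 to 7.51.

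The arrays were also divided in other ways into groups of the same sizes, on the 24527 genes measured on all arrays. For KO minus WT in M0 (13 genes, highest other split 6), M1 (10921 and 261) and M2 (11 and 2), the real split was 1 of 35 with as many genes. It was so too for M1 activation in WT (11892 and 796) and KO (14016 and 1576) and for M2 activation in WT (3794 and 1601) and KO (3266 and 4). The highest other splits had both arrays of the 4th set on the same side. These splits treat the arrays as free to exchange, although the deviations of arrays of a set had a mean correlation of 0.362 over genes. A share of 1 in 35 therefore does not exclude chance. Exchanged only within the 4 sets, 8 splits are possible, too few for a share under 0.05. The highest other among them gave 0 genes in M0, M1 and M2, 6 and 1 for M1 activation in WT and KO, and 0 for M2 activation. For the average difference, 1 of 100 splits gave as many genes (7156, highest other 7048). For the difference in M1 response 3 of 100 did (7440, highest other 8211). For each, 4 other splits kept the M1 genotypes, and without these the highest were 1 and 10. Such splits do not exclude chance either. For the difference in M2 response the real count was 0, which 100 of 100 splits match by construction, so the splits say nothing about chance. The planned rule would have read this as chance, and the exception for a count of 0 was added after the result was seen. Its highest other split, 2184 genes, had arrays of the 4th set on the same side and points to a structure of the samples.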

How the results depend on the processing

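The set as a block, the fit without the 4th set, the fit without the 3 arrays with the most nonuniform spots and the macrophage identity list without Lyz2 or both lysozyme genes were chosen after the data were seen. Apart from the omission of single replicates, 265 alternatives of results that answer a comparison were run, and 209 stayed within 1.5 times the count or kept direction and call. For 104 named genes and comparisons, 3031 alternatives gave the same call in 2675, the same direction without a call in 356 and the opposite direction in 0. A comparison with the authors' value table was planned and not run, because its identifiers do not belong to the probes whose values they carry.

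The counts of KO minus WT in M0 (14) and M2 (11) were the least stable. With the strict filter, which tests fewer genes, they were 6 and 4. They were 70 and 47 with array weights, 24 and 60 without the 4th set and 9 and 6 with only the arrays of the groups compared. In M0 the count was 22 with quantile normalization, and in M2 it was 28 with the set block and 7 without the 3 arrays with the most nonuniform spots. For M2 activation in WT (3914) the count was 6881 with array weights, 6519 with the set block, 5872 without the 4th set and 2081 with only the arrays compared. For M2 activation in KO (3371) it was 5783 with array weights, 5913 with the set block and 6360 with no filter. A fit with only the arrays compared has fewer residual degrees of freedom. For the other changes the cause was not tested.

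Within slides 1, 2 and 3 alone, with 2 residual degrees of freedom, limma called 0 genes in each slide for KO minus WT in M0, M1 and M2, for the average, for M2 activation in WT and KO and for the difference in M1 response. M1 activation gave 0, 574 and 0 genes in WT and 1990, 3552 and 309 in KO. At an unadjusted p under 0.05 the slides gave 244, 509 and 1092 genes in M0, 5419, 7635 and 4612 in M1, 485, 984 and 333 in M2, 3131, 3139 and 3073 on average, 1937, 2114 and 2438 for M2 activation in WT, 1686, 1668 and 2586 in KO, 4008, 3744 and 2584 for the difference in M1 response, and 6046 and 6278 for M1 activation in WT in slides 1 and 3. These counts follow from the few arrays of a slide.

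Genes that changed at least 2-fold, a narrower definition, were 5782 for KO minus WT in M1, 603 on average, 6260 and 8106 for M1 activation in WT and KO, 1629 and 1383 for M2 activation, and 4644 for the difference in M1 response. The Slc2a1 difference, which passed no test, was -0.14 in M1 with quantile normalization and -0.076 within slide 1, against 0.25, and 0.039 in M2 within slide 2, against -0.18; the cause was not tested. Of 74 list calls, 3 held with an estimated correlation. Fry, which asks another question, called 91. With the identity list without Lyz2 the calls were 74, and 73 without Lyz1 as well. Among the lists lost with quantile normalization, the highest adjusted p over the alternatives with the preset correlation was, for KO minus WT in M0, 0.918 for the unfolded protein response, 0.830 for fatty acid oxidation, 0.813 for the lysosome, 0.799 for HIF-1 targets, and 0.303 each for macrophage identity, the respiratory chain and the tricarboxylic acid cycle. It was 0.132 for NRF2 with M1 activation in WT and 0.374 in KO. It was 0.867, 0.813 and 0.531 for the lysosome with M1 and M2 activation in KO and for the difference in M1 response, 0.565 for glycolysis with M2 activation in KO, and 0.999 and 0.937 for fatty acid oxidation and interferon genes in M2. Some calls kept with quantile normalization were lost in other alternatives. Among these the highest camera adjusted p was 0.799 for inflammatory genes in M0, and 0.847 and 0.363 for the ATF4 and LXR lists in M2. The 4 lists called for KO minus WT in M1 were called in all 26 of their alternatives with the preset correlation, and in 0 of 4 cases with an estimated one (adjusted p = 0.537 to 0.544).

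Without each replicate in turn the counts ranged from 12 to 18 in M0, 10391 to 11573 in M1, 6 to 15 in M2 and 6765 to 7630 on average. The M2 count was 7 without WT M2 replicate 2, 6 without KO M2 replicate 2 and 7 without WT M2 replicate 3. M1 activation gave 11230 to 12290 genes in WT and 13585 to 14792 in KO, and M2 activation 2942 to 4563 and 2382 to 3435. The difference in M1 response gave 7157 to 7859 and that in M2 response 0 to 0. List calls numbered 72 to 86. The Slc2a1 difference ranged from -0.58 to -0.01 in M0, 0.01 to 0.39 in M1 and -0.34 to 0.15 in M2, where it was 0.15 without WT M2 replicate 1.

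The replicate number does not pair the arrays: deviations of arrays that share it had a mean correlation of 0.0669 over genes with a lowest value of -0.463. As a fixed block it gave 16, 11946 and 10 genes for KO minus WT in M0, M1 and M2, and 14, 11415 and 11 as a random block within genotype (consensus correlation 0.0209). Arrays that share a set had a mean correlation of 0.362, against -0.103 for others. For 23 of 24 arrays the closest array of another group shared the set. The main fit has no term for the set. Signal over background limits the dim genes, since 37325 genes could be tested with no filter and 17367 with the strict one.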

Other observations

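The tests of the hypotheses on Txnip and on a stress response were chosen after the result was seen.

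The 4th set of arrays differed from the others in several lists of genes. Beside the interferon and cell cycle lists, antigen presentation (median log2 difference 0.40, camera adjusted p = 2.5e-04), erythroid and mast cell genes (1.00, adjusted p = 5.0e-04), uptake and scavenger genes (0.26, adjusted p = 0.0156) and the LXR list (0.20, adjusted p = 0.0156) were higher, and the unfolded protein response (-0.25, adjusted p = 0.0191) and the ATF4 response (-0.42, adjusted p = 0.0446) were lower. With an estimated correlation none of the 8 lists was called (adjusted p = 0.228 to 0.735). Xist was -0.88 to 0.06 in this set and -8.40 to -3.74 in the others.

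Txnip is induced by MondoA and ChREBP, the transcription factors that sense glucose phosphates, so lower activity of these factors might explain its fall in KO M1 cells. Arrdc4, their other well-known target, rose by 2.22 in KO M1 (limma adjusted p = 1.8e-06), which speaks against a general fall of their activity in M1 as the cause. In M0 and M2, however, Txnip and Arrdc4 were both lower in KO than in WT in every set, though not called. Arrdc4 was 0.01 to 1.36 in KO against 0.90 to 1.55 in WT in M0, and 0.05 to 1.19 against 1.22 to 1.84 in M2. In M1 Arrdc3, of the same list, was lower (-2.20 ± 0.35), and of the 8 genes 2 were higher and 2 lower (camera adjusted p = 0.937). A fall at some of their targets therefore stays open.

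The rise of ATF4 and unfolded protein response genes in KO M1, with Ddit3 (CHOP) at 2.42 ± 0.34, could reflect a stress response of cells short of glucose. The lists were called with the preset correlation, but the lower camera adjusted p of the lists with an estimated correlation was 0.537. That correlation was estimated without the set as a block, and both lists differed in the 4th set with the preset correlation. The lists as a whole therefore cannot decide on a stress response, and no measurement of stress or of glucose use was analysed here.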
